A study of Mus musculus with 2 samples.

How the data were processed

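Single cells were sorted from kidneys of mouse embryos at embryonic day 18.5; 7 of 11 embryos of the litter carried the Six2-GFP transgene. Per the labels' protocols, tissue was dissociated with trypsin, scatter gates removed red blood cells and selected live single cells, and cells went into wells with lysis buffer, oligo-dT primer and spike-in RNA. The deposited table of raw read counts has 23420 genes and 576 cells, with 288 cells in each of 2 samples on 6 plates. A second deposited table holds the authors' normalized values, here called the normalized signal; in all 576 cells it equals the counts divided by 1 factor per cell, within a relative tolerance of 1e-09, and the factor ran from 0.00159 to 8.07 (median 1.54). The submitters' processing notes name TopHat2 2.1.0, TopHat, SAMtools, HTSeq 0.6.1p1 and DESeq2 and the build mm10, without the role of each; the annotation and the strand setting of the counting are not given in the sources used here. Genes that share reads with near-identical copies, and antisense partners, are therefore uncertain. Spike-in, GFP and mitochondrial rows were not found by name among the genes and so were not analysed. Isoforms were not analysed here either. Of the gene symbols, 93.0% were found in GENCODE vM21, from which coordinates (mm10) were taken. Each column was tied to a sample by the sort written in its name, which fits 1 sample's title.

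The main values rest on the raw counts. Cells with at least 50000 counts and 1000 genes were kept, 547 of 576; 13 Six2-negative and 16 Six2-positive cells were left out, of which 14 were on plate 12. Rn45s, a ribosomal RNA precursor, took 13.8% of all counts and over 30% in 19 cells, 16 of them Six2-negative. Median counts per cell were 805422 on plate 9 and between 1337963 and 1671653 on the other 5 plates. Counts were summed over the cells of a sort or class and scaled to counts per 1e6 counts (CPM). Ratios are log2, Six2-positive over Six2-negative or class over cap mesenchyme-like class, with a floor of 3 counts for genes under it. No p-value was computed, because each sort is 1 sample and cells are not replicates. Intervals are 95% exact Poisson for sums, exact binomial for ratios of sums and Clopper-Pearson for shares. Shares of cells with a read were computed after thinning each cell to 50000 counts with a fixed seed. The spread over 9 pairs of 1 plate of each sort describes technical variation only.

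Gene lists, markers, alternatives and the rule for named genes were fixed before the data were examined. There are 24 lists: 12 of cell type markers (cap mesenchyme, early nephron, podocyte, proximal tubule, loop and distal tubule, ureteric and collecting duct, stroma, mural and mesangial, endothelial, immune, erythroid, and 1 more whose result is not reported here) and 12 tested lists (epithelial, mesenchymal, splicing regulators, isoform switch hosts, S phase, G2/M, glycolysis, fatty acid oxidation, dissociation stress, basement membrane, signalling, and transcription factors of nephron progenitors). Of their 326 genes, 4 were not matched to the tables. Members under 1 CPM in both groups were left out of medians. A list's median was placed among 10000 random lists of the same size matched on mean expression in 10 bins. Named genes of the sort comparison are the 12 highest and 12 lowest ratios among genes with at least 20 CPM and a read in at least 20% of thinned cells in the higher sort, without gene models lacking a proper name, plus list members.

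Cells were clustered with scanpy 1.11.5 (Leiden on log counts per 10000, 2000 variable genes, 20 principal components, 15 neighbours, resolution 1, fixed seed), with Six2 and the tested lists left out. A cluster was named from at least 3 leading markers of 1 list. The scoring rule (at least 20 CPM, a read in 30% of cells and a log2 fold of 1) was set after the data were seen. Six2, though left out of the clustering, counted as a cap mesenchyme marker in the naming. No doublet caller was run, because cells were sorted singly into wells; an alternative left out the 5% of cells with most genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. On counts simulated for the sort comparison (23420 genes, 100 cells per group), 200 of 200 changed genes had the right direction. Within 0.5 of the true log2 ratio were 50 of 50 genes changed by 1, 46 of 50 by -1, 47 of 50 by 2 and 50 of 50 by -2. Apart from these cells, intervals covered the true ratio in 95.2% of 2000 draws of Poisson counts with equal means. That does not test coverage for reads that are not independent or for differences between cells. In a simulation of 3 cell types, 180 of 180 cells were placed with their type. Those types were drawn from pooled profiles of cells chosen for high levels of marker genes, so well-separated types were built in.

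Alternatives changed 1 choice at a time: the way of averaging, the authors' normalized values, median-of-ratios scaling, cell and gene filters, thinning, each plate left out, and the settings of the clustering. Added after the data were seen were totals without Rn45s and Lars2, the class comparison without each plate and without cells rich in Rn45s, and the stroma-like class as reference.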

Results

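The tables hold gene-level read counts of 576 single cells from kidneys of mouse embryos at embryonic day 18.5, made with Smart-seq2, a method that copies whole polyadenylated transcripts from cells sorted into wells. The embryos came from a cross that carried a Six2-GFP transgene, whose fluorescence marks the cap mesenchyme, the progenitor tissue of the nephron. Cells were sorted by fluorescence into a Six2-positive and a Six2-negative sample, with the gate set on kidneys without the transgene. Each sample was spread over 3 plates of 96 cells. After the cell filter, the Six2-positive sample had 272 of 288 cells and 408712524 counts, with a median of 1456323 counts and 7342 genes per cell. The Six2-negative sample had 275 of 288 cells and 359193614 counts, with a median of 1241895 counts and 7289 genes per cell. There was 1 sample per sort and no replicate, so no difference below has a replicate check or a p-value. Plates are technical portions of a sample, and every plate held 1 sort, so that plate and sort cannot be told apart. The 95% intervals (exact Poisson for counts, Clopper-Pearson for shares) cover counting error only, since reads without molecular identifiers are not independent molecules. The series title names isoform switching during kidney development; isoforms were not analysed here, and the comparisons below concern gene levels.

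The sort was checked first on Six2, the homeobox gene that keeps nephron progenitors undifferentiated. Six2 had 227 CPM, counts scaled to the total over the sample's genes, (226 to 229) in the Six2-positive sample and 1.57 (1.45 to 1.71) in the Six2-negative sample, a log2 ratio of 7.18 (7.06 to 7.30) or 145-fold. Its level ran from 207 to 263 over the Six2-positive plates and from 1.42 to 1.62 over the Six2-negative plates. After each cell was thinned to 50000 counts, 96.0% (92.9 to 98.0) of Six2-positive cells and 4.73% (2.54 to 7.95) of Six2-negative cells had a Six2 read, and without thinning the shares were 98.9% and 32.0%. More than 10 Six2 reads were present in 97.4% of Six2-positive cells and in 7 Six2-negative cells (2.55%). Six2 lies on chromosome 17 from 85684277 to 85688274 on the minus strand (mm10, whole gene).

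The comparison between sorts shows what sets GFP-marked progenitors apart from the rest of the kidney. The 12 highest ratios in the Six2-positive sample included genes of the progenitor state and its signals. Fgf20, a growth factor made by nephron progenitors, had 49.6 CPM against 0.103 (log2 ratio 8.91, 8.45 to 9.42), and Eya1, a coactivator that works with Six2, 597 against 8.43 (6.15, 6.09 to 6.20). The 0.103 of Fgf20 rested on 37 counts, 89.2% of them in 1 cell. It ran from 0 to 0.237 over the Six2-negative plates, so the interval of its ratio is too narrow. Osr1, a transcription factor of the early kidney field, had 98.0 against 1.86 (5.72), and Six3, a relative and chromosomal neighbour of Six2, 130 against 2.41 (5.76). Six3 overlaps an antisense gene, Six3os1, and the counting strand is not stated, so part of its reads may belong to that gene. The reads assigned to Six3os1 came to 4.58 CPM in Six2-positive cap mesenchyme-like cells, next to 132 for Six3. The others of the 12 highest genes were Has2, a hyaluronan synthase (7.42), Nxph1 (6.67), Hoxd12 (6.50), Bmper, a binder of bone morphogenetic proteins (6.35), Fam19a2 (6.20), Crym, which binds thyroid hormone (5.95), and Ocm, a calcium-binding protein (5.54). After thinning, an Eya1 read was present in 97.1% of Six2-positive and 7.64% of Six2-negative cells, and a Fgf20 read in 30.1% and 0.727%.

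The 12 lowest ratios, those of genes higher in the Six2-negative sample, included genes known from tubule and collecting duct epithelium. They were taken among genes with a read in at least 20% of thinned Six2-negative cells, and so do not stand for all genes higher in that sample. Calb1, a calcium-binding protein of the ureteric bud and distal tubule, had 1038 CPM against 0.355 in the Six2-positive sample (log2 ratio -11.52, -11.76 to -11.28). Cldn8, a tight junction protein, had 417 against 0.147 (-11.47), and Gata3, a transcription factor of the ureteric lineage, 200 against 0.0905 (-11.11, -11.61 to -10.64). Muc1, a mucin of apical membranes, had 48.0 against 0.00979, which rests on 4 counts (-12.26, -14.13 to -10.90). The others of the 12 lowest ratios were Wfdc15b (-11.72), Ehf, an epithelial transcription factor (-11.53), Slc44a4 (-11.41), Pou3f3 (-11.25), Pkhd1, the gene of recessive polycystic kidney disease (-11.22), Prr15l (-11.20), Tspan8 (-11.16) and Dclk3 (-11.06).

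Gene lists fixed beforehand gave the same division by cell type. All 10 measured cap mesenchyme markers, among them Six2, on which the sort rests, were at least 2-fold higher in the Six2-positive sample. Their median log2 ratio was 3.80, above all 10000 matched random lists (3.45 to 4.52 over 9 pairs of plates). Cited1, a cofactor of self-renewing progenitors, had 76.5 against 4.55 CPM, and Meox1 32.1 against 2.16. Of 13 measured transcription factors of nephron progenitors, 9 were at least 2-fold higher and 1 at least 2-fold lower (median 1.77, above all random lists). They included Sall1 at 321 against 84.9 and Hoxa11 at 95.9 against 21.7, whereas Wt1 was nearly equal at 373 against 387. Markers of other tissues were lower in the Six2-positive sample, with medians of -10.66 for 10 loop and distal tubule genes, -10.61 for 12 ureteric and collecting duct genes, -5.69 for 12 proximal tubule genes and -4.18 for 10 podocyte genes. The medians were -6.99 for 12 endothelial genes, -6.95 for 12 immune genes, -3.50 for 12 stroma genes and -2.91 for 10 early nephron genes. Each of these 8 medians lay below all random lists, and that of 7 mural and mesangial genes, -3.07, at percentile 0.51. Some varied widely over the 9 pairs of plates, though each range stayed negative. They ran from -9.81 to -3.77 for proximal tubule, -11.34 to -4.68 for immune, -4.87 to -2.05 for stroma and -4.84 to -1.56 for mural and mesangial genes. Exceptions within the lists were Fgf8 at 1.89 against 0.568, Hsd11b2 at 106 against 62.7, Foxd1 at 12.4 against 7.40 and Wnt4 at 34.2 against 21.2, each higher in the Six2-positive sample. Of the erythroid list only Alas2 was measured (-4.41, percentile 6.11), and its members Hbb-bs and Hbb-bt had no match by name. Beta-s, a beta-globin gene, took over 5% of the counts of 6 Six2-negative cells, up to 52.6%, although scatter gates had been set against red blood cells. In Six2-positive cells Beta-s took at most 0.00169% of a cell's counts.

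Epithelial genes were lower in the Six2-positive sample as a group. All 16 measured members were at least 2-fold lower, with a median of -7.97, below all random lists (-8.34 to -7.09 over plate pairs). Cdh1, the gene of E-cadherin, had 0.0807 against 166 CPM (-11.01), and Cdh16 0.670 against 719 (-10.07). Epcam, an epithelial adhesion gene, was not absent from the Six2-positive sample, at 28.0 against 516 (-4.20). The 14 mesenchymal genes did not share a direction (5 higher, 4 lower, median 0.25, percentile 91.3). Cdh2, the gene of N-cadherin, was higher at 174 against 19.4 (3.17), while Fn1, fibronectin, was lower at 12.7 against 214 (-4.08), as was Vim at 98.1 against 232 (-1.24). Of 13 basement membrane genes, 10 were at least 2-fold lower (median -1.72, below all random lists), among them Lama1 at 2.64 against 108 (-5.36).

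Among 30 measured splicing regulators, 3 were at least 2-fold higher and 8 at least 2-fold lower in the Six2-positive sample. Esrp1 and Esrp2, which drive epithelial splicing, had 0.0245 against 33.0 (-10.40, -11.46 to -9.52) and 0.0514 against 26.1 (-8.99), and Rbm47 5.98 against 108 (-4.18). Rbfox1, a splicing regulator known from neurons and muscle, had 27.0 against 2.48 (3.44, 3.34 to 3.54), and Rbm24, known from muscle, 15.3 against 0.445 (5.10). Hnrnpa1 was also higher (1.71), with an uncertain level because near-identical copies share its reads. The median of the list was 0.17 (percentile 89.9) and its mean -0.66; with the authors' normalized values, which moved the median of all genes by -0.33, the list median was -0.10. Of 17 host genes of known isoform switches, 1 was higher and 2 lower (median -0.14, percentile 12.9). Cd44 had 186 against 27.6 (2.75), Nedd4l 5.88 against 115 (-4.29) and Fgfr2 122 against 250 (-1.04).

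Of the lists of general cell state, only fatty acid oxidation lay outside the middle 95% of random lists. None of 17 S-phase and 18 G2/M genes reached a 2-fold difference (medians 0.14, percentile 73.1, and 0.03, percentile 43.3). Glycolysis had a median of 0.13 (14 genes, percentile 65.1, mean -0.03), with Hk2, a hexokinase, at 1.72 and Pfkp at -2.42. Fatty acid oxidation had a median of -0.43 (14 genes, percentile 1.61; -0.66 to -0.27 over plate pairs), with Ppargc1a, a regulator of mitochondrial genes, at 0.624 against 58.8 CPM (-6.56). Genes of dissociation stress had a median of -0.09 (12 genes, percentile 18.4), with Fosb at 1.16 and Atf3 at -2.11. The list of Wnt, Notch, Fgf, Bmp and Ret signalling had a median of 0.09 (22 genes, percentile 65.3), with Axin2, a Wnt target, at 1.76 and Lef1, a Wnt effector, at -3.16. Elavl4, an RNA-binding protein known from neurons, was higher at 42.6 against 2.73 CPM (3.96, 3.87 to 4.06).

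**Figure D1:**
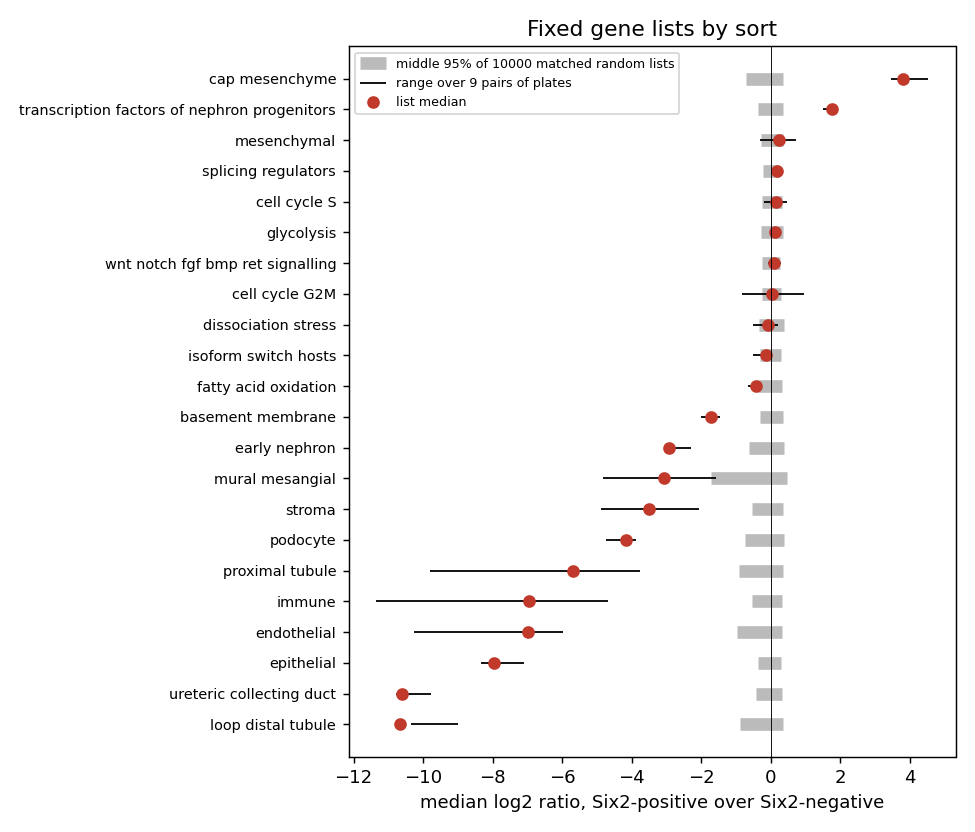
Median log2 ratio of each fixed gene list with at least 5 measured members, Six2-positive over Six2-negative (x axis, log2). Red points are list medians, grey bars the middle 95% of 10000 matched random lists and black lines the range over 9 pairs of plates; cap mesenchyme stands at 3.80 and epithelial genes at -7.97.

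Clustering with Six2 and the tested lists left out gave 13 clusters. Cap mesenchyme-like cells made up 97.4% (94.8 to 99.0) of the Six2-positive sample and 1.45% (0.398 to 3.68) of the Six2-negative sample, or 265 and 4 cells. The Six2-negative sample held ureteric/collecting duct-like cells (24.4%, 19.4 to 29.9), stroma-like cells (18.2%, 13.8 to 23.3), immune-like cells (10.2%, 6.87 to 14.4), podocyte-like cells (9.09%, 5.97 to 13.1), proximal tubule-like and loop/distal tubule-like cells (7.64% each, 4.79 to 11.4) and endothelial-like cells (4.00%, 2.01 to 7.04). Cluster 0, with 17.5% (13.2 to 22.5), was led by as many early nephron as proximal tubule markers, 8 of each, and was left without a class name. The Six2-positive sample held 3 immune-like cells, 2 stroma-like cells and 2 cells of cluster 0; for each of the other classes it held 0 of 272 cells, with an upper bound of 1.35%. The GFP gate sets these shares, and with 1 sample per sort a cluster mostly of 1 sample may be that sample rather than a type. Beta-s and Alas2 were among the leading genes of the immune-like cluster, whose 31 cells included all 6 cells rich in Beta-s. That cluster was shallow, with median counts per cell of 541262, or 43.6% of the median of the Six2-negative sample. Beta-s was also among the leading genes of the proximal tubule-like cluster, with up to 2.88% of a cell's counts. Of the Six2-positive cells, 265 had over 10 Six2 reads, 261 of them cap mesenchyme-like, so some Six2-positive cells of other classes held Six2 too. The immune-like class had 35.8 CPM of Six2, though its 28 Six2-negative cells had at most 3 Six2 reads each. No class had 10 cells in each sort, so no comparison of the sorts within a class was possible.

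**Figure D2:**
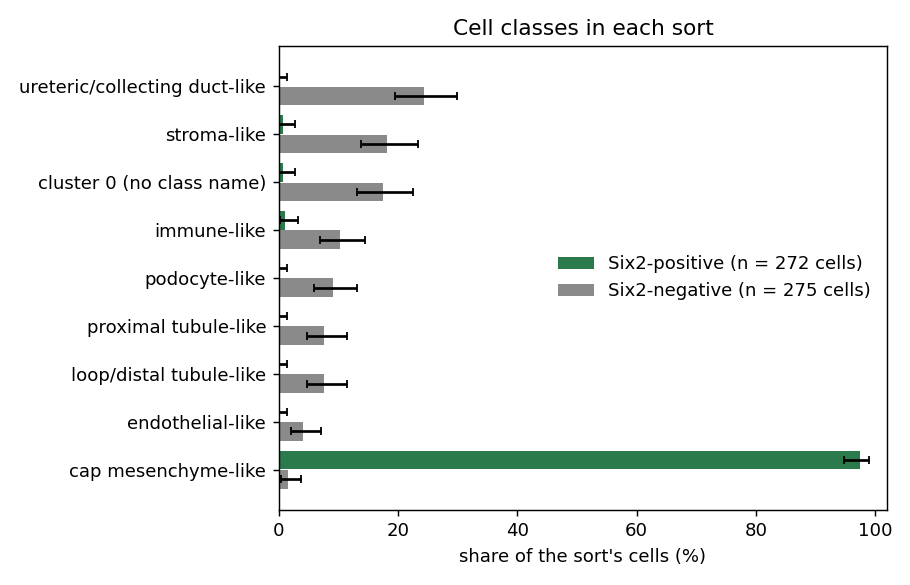
Share of each sort's cells in each class (x axis, percent), with green bars for 272 Six2-positive and grey bars for 275 Six2-negative cells and Clopper-Pearson 95% intervals as error lines. Cap mesenchyme-like cells make up 97.4% of the Six2-positive and 1.45% of the Six2-negative sample.

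The tubular, podocyte-like and stroma-like classes and cluster 0 were then set against the cap mesenchyme-like class, from which most of the nephron derives. The ureteric and stromal lineages do not derive from it, so that for those classes the contrast is between lineages. Epithelial genes were higher in the tubular classes. All 16 measured members were at least 2-fold higher in ureteric/collecting duct-like cells (median log2 ratio 8.88) and in loop/distal tubule-like cells (8.36), as were all 15 in proximal tubule-like cells (7.95) and all 14 in cluster 0 (4.95). In podocyte-like cells only 2 of 7 were (median 0.24, percentile 85.0), and in stroma-like cells 3 of 6 (-0.05). Cdh1 had 346 CPM in ureteric/collecting duct-like, 319 in loop/distal tubule-like and 127 in cluster 0 cells, against 0.0838 in cap mesenchyme-like cells. Mesenchymal genes were lower in ureteric/collecting duct-like cells (11 of 14, median -4.13), loop/distal tubule-like cells (10 of 13, -7.03), proximal tubule-like cells (11 of 13, -3.16), cluster 0 (9 of 13, -1.70) and podocyte-like cells (7 of 13, -1.17), and higher in stroma-like cells (8 of 14, 1.63). Vim, an intermediate filament gene, had 521 CPM in podocyte-like and 604 in stroma-like cells, against 101 in cap mesenchyme-like and 2.37 in ureteric/collecting duct-like cells. Nearly all cap mesenchyme-like cells were on the Six2-positive plates and nearly all cells of the other classes on the Six2-negative plates, which leaves this contrast bound to plate. Stroma-like cells, nearly all of the same plates, were a reference chosen after the data were seen. Against them epithelial genes were higher by a median of 9.55 in ureteric/collecting duct-like, 8.67 in proximal tubule-like, 8.26 in loop/distal tubule-like and 5.47 in cluster 0 cells. In podocyte-like cells the median was -1.54 (6 genes, 2 at least 2-fold higher and 4 lower).

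As a list, the splicing regulators were lower in proximal tubule-like cells (13 of 30 at least 2-fold lower and 6 higher, median -0.74, percentile 0.65; -0.72 against stroma-like cells) and within the middle 95% of random lists in the other 5 classes, while single members differed by class. Esrp1 had 87.4 CPM in ureteric/collecting duct-like and 91.2 in loop/distal tubule-like cells, 3.17 in cluster 0 and 0.0247 in cap mesenchyme-like cells, and had 0 counts in 21 proximal tubule-like cells. Esrp2 was present in all epithelial classes, at 42.8 in proximal tubule-like, 77.8 in loop/distal tubule-like, 32.0 in ureteric/collecting duct-like and 23.4 in podocyte-like cells, against 0.187 in cap mesenchyme-like cells. Rbm47 was highest in proximal tubule-like cells at 327 and low in podocyte-like cells at 2.88 and stroma-like cells at 1.04. Rbfox1 had 27.2 in cap mesenchyme-like cells, against 0.354 in ureteric/collecting duct-like and 0.0882 in stroma-like cells, and was less far below in podocyte-like cells (log2 ratio -1.18). Ptbp3 was higher in ureteric/collecting duct-like (368) and podocyte-like cells (341) than in cap mesenchyme-like cells (96.8). The other list medians were -0.19 in ureteric/collecting duct-like cells (percentile 15.1), -0.19 in loop/distal tubule-like cells (13.1), -0.47 in podocyte-like cells (2.68), -0.13 in stroma-like cells (29.8) and -0.00 in cluster 0 (48.2). Among the host genes of isoform switches, Fgfr2 had 625 in ureteric/collecting duct-like and 123 in cap mesenchyme-like cells, and Cd44 11.5 and 186; the list median in ureteric/collecting duct-like cells was 0.25 (percentile 94.8). Esrp1 lies on chromosome 4 from 11331933 to 11386783 (minus strand), Esrp2 on chromosome 8 from 106130319 to 106136974 (minus strand) and Rbfox1 on chromosome 16 from 5885355 to 7411526 (plus strand), each as a whole gene in mm10.

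**Figure D3:**
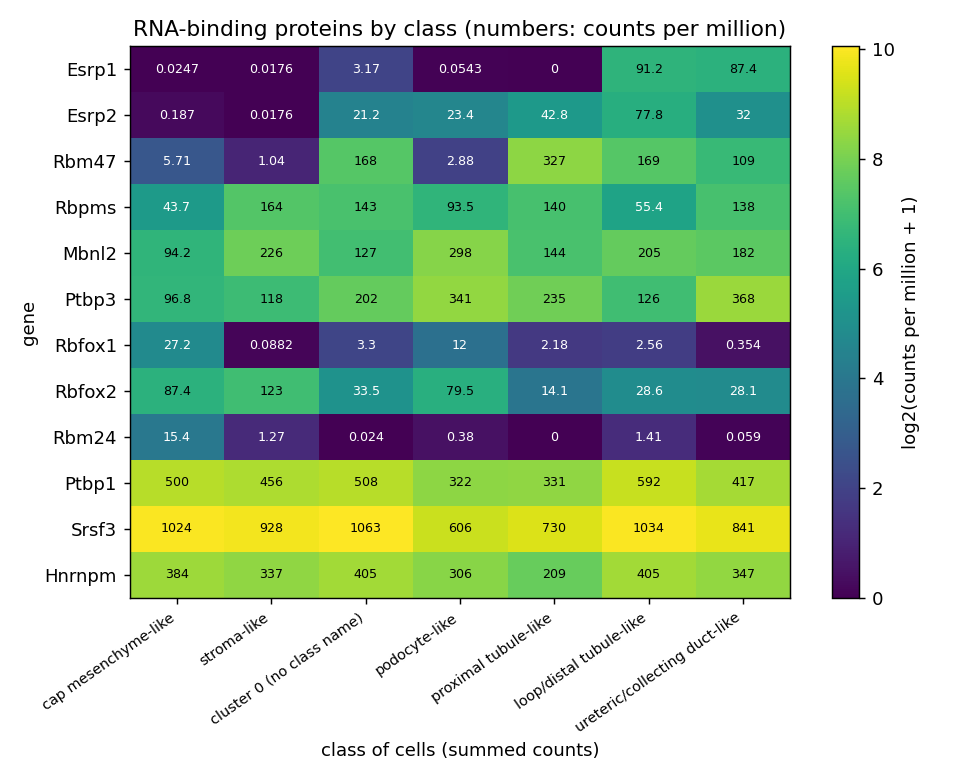
Summed CPM of 12 RNA-binding proteins (y axis) in 7 classes of cells (x axis), as numbers and as color on a log2 scale after adding 1. Esrp1 stands at 87.4 in ureteric/collecting duct-like and at 0 in proximal tubule-like cells, and Rbfox1 at 27.2 in cap mesenchyme-like cells.

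Proximal tubule-like and podocyte-like cells were below the sum of cap mesenchyme-like cells in genes of proliferation. All 18 G2/M genes were at least 2-fold lower in both (medians -6.18 and -6.80), as were 15 of 17 S-phase genes in proximal tubule-like (-2.83) and 16 of 17 in podocyte-like cells (-2.95). At Leiden resolution 0.5, where the proximal tubule-like class also took in cluster 0, its S-phase median was 0.32. In cluster 0 itself S-phase genes were higher (3 of 17 at least 2-fold, median 0.65, 0.17 to 0.87 over plate pairs). Top2a, a topoisomerase of dividing cells, had 0.419 and 8.28 CPM against 222. That reference was carried by 1 of its 4 clusters, cluster 8 with 40 of 265 Six2-positive cells, at 1120; clusters 10, 11 and 12 had 13.1, 1.88 and 72.9, so the other clusters were below 222 as well. Fatty acid oxidation was higher in proximal tubule-like cells (9 of 14 genes, median 1.37, percentile 99.9), with Acadm, a medium-chain acyl-CoA dehydrogenase, at 833 against 62.4, in loop/distal tubule-like cells (0.90), with Ppargc1a at 223 against 0.629, and in cluster 0 (0.44, percentile 99.0). Glycolysis was lower in podocyte-like (median -0.69, percentile 1.00; -0.17 against stroma-like cells) and stroma-like cells (-0.41, 2.31) and higher in ureteric/collecting duct-like cells (0.36, 97.9), but did not shift as a list in proximal tubule-like cells (3 of 14 higher and 3 lower, -0.26, 33.1), where Pkm was lower at 152 against 956 and Pfkp higher (3.95). Basement membrane genes were higher in all 6 classes compared, with medians of 2.06 in ureteric/collecting duct-like, 1.90 in podocyte-like (12 of 13), 1.73 in cluster 0, 1.34 in proximal tubule-like, 1.15 in loop/distal tubule-like and 1.10 in stroma-like cells. Against stroma-like cells, nearly all of the same plates, they were smaller, at 0.66, 1.02, 0.47 (4 higher, 4 lower), 0.33 and 0.52 for the first 5. Podocyte-like cells had Col4a3 and Col4a4, collagen chains of the glomerular membrane, at 296 and 239 against 0.355 and 0.214. Transcription factors of nephron progenitors were lower in every class compared, from -1.69 in cluster 0 to -3.90 in proximal tubule-like cells; against stroma-like cells cluster 0 was at 0.65 (4 higher, 4 lower), podocyte-like cells at -0.71 and proximal tubule-like cells at -2.70. Wt1 was higher in podocyte-like cells at 3081 against 383 in cap mesenchyme-like cells (3.01). Stress genes were lower in cluster 0 (9 of 12, median -1.45), with Fos at 819 against 2781, in loop/distal tubule-like cells (7 of 12, -1.17) and in stroma-like cells (3 of 12, -0.79); against stroma-like cells the first 2 were at -0.53 (4 of 12 lower) and -0.27 (2 higher, 2 lower). The G2/M median of loop/distal tubule-like cells, 0.93, ran from -2.43 to 3.28 over pairs of plates, so no direction is read from it.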

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

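Chosen after the data were seen were the totals without Rn45s and Lars2, the class comparison without each plate, and that without cells rich in Rn45s. Over all alternatives, 1865 of 2137 values moved by less than 1 SD over pairs of plates (for shares, stayed within the binomial interval), 267 moved further with their direction kept or too near 0 to have one, and 5 changed sign. Plates are technical, so this spread says nothing about other animals. Only the main clustering gave a cluster with the tied markers of cluster 0. The share and list medians of cluster 0 were therefore not followed where cells were clustered anew, and those cases are not in the counts. A class named early nephron alone came at resolution 2, with 4000 variable genes, the authors' values, all genes allowed, another seed, no cell filter or a stricter one. None came at resolution 0.5, with 10 principal components or without the 5% of cells with most genes. Whether its cells were those of cluster 0 was not compared. The authors' normalized values shifted the median of all genes by -0.33, to -0.41, and the other scalings by 0.07 or less. With them the medians by sort were -0.10 for splicing regulators, -0.15 for glycolysis (both counted as changed sign) and -0.23 for mesenchymal genes; with the shift of all genes taken out they were 0.23, 0.18 and 0.10, so neither sign changed relative to other genes. The Six2 ratio was 6.64 with the mean over cells, 6.26 with the authors' values, 6.59 after thinning and 7.58 without the 5% of cells with most genes. The cap mesenchyme median was 3.04, 2.74 and 3.09 under the first 3 of these. Thinning gave -6.66 for epithelial genes and 0.25 for splicing regulators, and leaving out plate 12 gave -7.56 for epithelial genes. Shares of cells with a read depended on depth, as 51 of their 96 alternative values (thinned to 100000 counts or unthinned) left the interval. Unthinned, Six2 reads were in 98.9% of Six2-positive and 32.0% of Six2-negative cells. An unthinned Eya1 read was in 36.7% of Six2-negative cells and a Fgf20 read in 40.1% of Six2-positive cells. With 10 principal components and without a cell filter, the ureteric/collecting duct-like medians were -0.11 and -0.12 for splicing regulators and -0.019 and -0.039 for stress genes, the latter with changed sign; the stricter filter gave 8.35 for epithelial genes. At resolution 0.5 the proximal tubule-like S-phase median was 0.32, with changed sign, where that class also took in cluster 0. Without a cell filter 93.8% of Six2-positive cells were cap mesenchyme-like. Apart from the cases with a stated reason, the cause was not tested. Not run were the spike-in and mitochondrial alternatives, which need rows not found by name here. The comparisons of the sorts within a class and of classes with cap mesenchyme-like cells of the same sort were also not run, since too few cells were present.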

Other observations

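The tests in this part were chosen after the result they measure had been seen, except those of muscle genes and of reads shared between Six3 and Six2 (its repeats with several reads taken as 1 came after), and the genes it names were chosen after their values were seen. The 265 Six2-positive cap mesenchyme-like cells lay in 4 clusters, each with cells on all 3 Six2-positive plates, and are compared here without the 4 Six2-negative ones, so that differences among them are not bound to sort. Of the tested lists, G2/M separated them most. Its median log2 ratio against the other cap clusters was 4.86 in cluster 8 and -1.69, -4.21 and -4.89 in clusters 12, 10 and 11. Top2a had 1120 CPM in cluster 8 against 13.1, 1.88 and 72.9 in clusters 10, 11 and 12. The list was left out of the clustering, but other genes of cell division, such as Espl1 among the leading genes of cluster 8, were not. This separation may therefore have been built in by the clustering. The reference of clusters 10, 11 and 12 includes cluster 8, which lowers their G2/M medians. The stress list was higher in cluster 11 (0.82) and lower in cluster 8 (-1.03), with Fos at 3997 and 1392, while no member reached 2-fold in cluster 10 (-0.05, percentile 23.7) or cluster 12 (-0.22, percentile 0.28), with Fos at 2791 and 2467. Tissue had been held at 37 degrees in trypsin, and stress genes are known to respond to dissociation.

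Cluster 12 did not differ from the other cap clusters in the list of transcription factors of nephron progenitors (median -0.05, percentile 18.5) or of signalling (-0.04, 24.0), but single genes stood apart. Osr1 had 52.6 CPM there against 115 in cluster 10 and 143 in cluster 11, whereas Mycn, a growth regulator, had 47.5 against 9.73 and 14.5, and Hey1, a Notch target, 46.2 against 19.1 in cluster 10. Lamb1, a laminin chain, had 174 against 77.1 in cluster 10 and 58.4 in cluster 11. Six2 itself was at 226, 219 and 260 in clusters 12, 10 and 11. Rbfox1 was lower in cluster 12 (20.5) and cluster 8 (13.6) than in clusters 10 and 11 (36.0 and 33.7).

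Six3 stood at 132 CPM in the Six2-positive cap mesenchyme-like cells, 116 to 143 over plates, next to 229 for Six2, from which it lies 54975 bases away on chromosome 17 (85613608 to 85629302, plus strand). Reads shared with Six2 would keep a fixed share. In 78.5% of cells the interval of the share left out the pooled 36.5%, but reads are not independent molecules. The figure fell to 45.3% with every 10 reads taken as 1 and to 1.13% with every 100. These cells had a median of 260 Six2 reads where present. With every 100 taken as 1, too few units per cell remained for an interval to leave out the pooled share, so that setting decides nothing. The true number of reads per molecule is not known, so shared reads stay open. Podocyte-like cells had 5.05 CPM for Six3 and 0.271 for Six2, so their Six3 reads exceeded what the pooled share would give. Immune-like cells had 9.49 and 35.8 and stroma-like cells 2.13 and 10.4, where Six3 fell below that share. After thinning, a Six3 read was in only 6.45% of immune-like and 3.85% of stroma-like cells, so these levels rest on few cells. The levels of other classes therefore do not decide the source in cap mesenchyme-like cells. In the Six2-positive cap mesenchyme-like cells, Six3 reads were not confined to a few cells, since 90.9% (86.8 to 94.1) had a Six3 read after thinning. RNA carried over from Six3-rich cells into many wells could also give a high share, so this test does not exclude it. As a hypothesis, the Six2-GFP transgene or its insertion site may drive Six3; this could not be told apart from expression of the gene in its own place. The test needs cap mesenchyme cells without the transgene, and only 2 cap mesenchyme-like cells of the Six2-negative sample had over 10 Six2 reads (248 Six3 and 230 Six2 reads in sum), with their genotype unknown and their small number known before the test.

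Rbfox1, Rbm24 and Elavl4, known mainly from neurons or muscle, had 27.4, 15.5 and 43.1 CPM in the 265 Six2-positive cap mesenchyme-like cells and a read in 46.8%, 23.0% and 43.0% of them after thinning. RNA of muscle does not account for Rbm24, as the median of 6 muscle genes was 0.304% of it; Acta1 had 0.0124 CPM and Ckm 0, though Tnnt3 had 2.58. RNA of neurons does not account for Elavl4, as the higher of Stmn2 and Tubb3 was 0.260% of it. The lowest plate had at least 60.9% of the highest plate's level for each gene, which argues against a single plate. RNA of neural cells other than neurons was not excluded and stays open. No biological explanation was tested.

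Outside the cap mesenchyme-like class, 31.4% (25.9 to 37.3) of 271 Six2-negative cells had a Six2 read, with a median of 1 read where present. Reads carried over from Six2-positive cells were tested as a source. Fgf20, Nxph1, Hoxd12 and Bmper stood in the same cells at a median fraction of their cap mesenchyme-like level 1.16 times that of Six2, within the 3-fold bound. The ratio was 0.367 without cells with over 10 reads of the gene, close to that bound, and single cells held from 34.1% to 89.2% of each gene's reads. A read of the 4 genes was present in only 1.48%, 7.75%, 4.06% and 9.23% of the cells, at cap mesenchyme-like levels of 43.7 to 152 CPM against 229 for Six2. Carry-over therefore stays open. Low expression kept in descendants of the progenitors would give nephron classes a higher share than unrelated classes. The difference was -8.89 percentage points, with 27.0% (19.1 to 36.0) against 35.8% (26.8 to 45.7), so the higher share was not seen, though the intervals overlap. The unrelated classes were ureteric/collecting duct-like, endothelial-like and immune-like cells, with a Six2 read in 38 of 106. Kept expression cannot be the source of the reads in those classes. For the nephron classes it remains open too.

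Col1a1, a stromal collagen gene, had 42.8 CPM in Six2-positive cap mesenchyme-like cells, 2.46% of its stroma-like level, and a read in 43.4% (37.3 to 49.6) of them after thinning. The other 11 stroma markers reached a median of 0.924% of their stroma-like level, 37.6% of the fraction of Col1a1, and ran from 0.0688% for Col3a1 to 38.5% for Foxd1, with Tcf21 at 9.15% and Lum at 3.27%.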
